A study of Mus musculus with 130 samples.

How the data were processed

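Gene expression was analysed in 10 RNA-seq libraries of mouse embryonic stem cells, each the single library of its group, so no replicate spread could be estimated. The other 120 of the 130 samples were not analysed here. Per the labels' protocols, total RNA was extracted from cells grown on gelatin and libraries were made by Smart-seq2, which amplifies full-length cDNA by PCR. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Whether counting used strand is not given in the sources used here, so a gene and an overlapping or antisense partner, such as Kcnq1ot1 and Kcnq1, cannot be told apart.

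Per the submitters' processing notes, reads were aligned with STAR 2.5.3a and counted with RSEM on GRCm38 (mm10), with the annotation release not given in the sources used here. The deposited values include expected counts per gene, in which RSEM shares out reads that match several genes, and a posterior standard deviation of each count. The deposited TPM values are scaled by RSEM for effective gene length and for the total of each library, per the file headers. Each library had 52550 genes, and 4.26% to 6.17% of its expected counts were not whole. Gene symbols were found for 99.7% of gene IDs, and the 147 IDs without a symbol held at most 0.067% of the counts of a library. Coordinates and gene types came from a RefSeq table of the same build, which held 71.8% of all genes and 95.3% of those at 1 CPM or more. Sharing of reads affects near-identical families most, so single members of the Magea, Xlr, Rhox2, Zscan4, Usp17l and histone families are uncertain, and a list is safer to read than a member.

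Expected counts were rounded to whole numbers and scaled to CPM, the count relative to the effective library size, with TMM factors computed over all 10 libraries with edgeR 4.0.16. Differences are log2(CPM + 1), and folds are ratios of CPM without a pseudocount. A gene was counted as higher or lower when its log2 difference was at least 1, its CPM at least 1 in either library, and the exact 95% conditional binomial (Clopper-Pearson) interval of the count ratio excluded 1. Where a library had 0 counts, the fold was computed against a floor of 3 counts in that library, which is 0.118 to 0.236 CPM, and written as at least that fold. Total counts of 11436808 to 25609600 per library set this precision, and the library labelled G9a/GLP DKO, the shallowest, has the highest floor. The rule describes libraries, not conditions. In tests on simulated counts for 52550 genes with 200 genes changed in each of the 11 comparisons, 98.5% to 100.0% of genes changed 3-fold and 100.0% of genes changed 6-fold were recovered, 0% of genes changed 1.5-fold were, and 0 unchanged genes were called. The intervals covered the simulated ratio for 93.0% to 98.0% of the changed genes. The simulated libraries carried counting error only, with no other difference between them. The 0 unchanged genes called therefore do not measure how often such genes are called in these libraries. A 1.5-fold change lies under the log2 threshold of 1, so its recovery of 0% was set by the rule. The changed genes were taken only from genes well above the minimum of 1 CPM, so recovery and coverage were not tested for low-expressed genes. Near that minimum a 3-fold change can fall short of a log2 difference of 1, because 1 CPM is added to both libraries.

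The groups, the comparisons, the size rule, 26 gene lists and the rule for named genes were fixed before the data were examined, and 2 lists (hypoxia-inducible genes, and Pramel and Nlrp4 genes) were added later. The Xlr list was matched by the start of the symbol and also takes Slx1b, Slx4, Slx4ip and Slxl1. Named genes were the targeted genes, the 8 largest higher and 6 largest lower protein-coding genes with at least 10 CPM and a standard symbol (4 each way between mutants and between wild types), and up to 4 members with the largest difference from each list with at least 3 measured members. A paragraph may print fewer, from the top. One gene that this rule selected is not reported here. For each list, the median difference was placed by percentile among 10000 random lists of the same size matched on mean expression in 20 bins and drawn from genes past the same minimum. These random lists were drawn gene by gene and do not carry the sharing of reads within near-identical families. Percentiles of lists that hold such families may therefore be too extreme. A list member is measured when it has at least 1 CPM in either library, so a member under 1 CPM in the control can be counted only when higher. List members were therefore also counted with no minimum, by whether the counting interval of the ratio excluded 1, a choice made after seeing the data. The median at the floor is the median log2 ratio with no pseudocount and with counts under 3 raised to 3 in both libraries. Chromosome medians were taken over genes with at least 10 CPM in either library.

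Comparisons that share a control were also set against 100 simulated pairs of unchanged libraries, which carry counting error only, and against the overlap of independent lists. Independent lists take the rate over all genes measured. Genes under 1 CPM in the control can be counted only as higher, so these values may be too low for higher genes. The alternatives tried were DESeq2 1.42.0 size factors, total count only, deposited TPM, pseudocounts of 0.1 and 5 CPM, a minimum of 5 CPM and no minimum, chromosome medians at 1 CPM, and the other wild-type TT2 library as control. Chosen after seeing the data were WT J1 and WT TT2 as controls of the other set and the counts without chromosomes 1, 8, 11 and Y.

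The inhibitor libraries differed from the other 6 in library-wide measures, and whether preparation or the cells set these was not tested. The difference between gene length and effective length was 251 to 275 bases in the 4 inhibitor libraries and 149.8 to 198 in the others, ribosomal protein genes took 3.20% to 3.67% against 6.60% to 9.71% of counts, and mitochondrially encoded genes 1.49% to 2.12% against 2.68% to 5.05%. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.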

Results

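Gene expression was measured by RNA-seq in mouse embryonic stem cells, the self-renewing cells derived from the inner cell mass of the blastocyst, grown on gelatin with serum and leukemia inhibitory factor. The 10 libraries fell into 10 groups of 1 library each. 3 came from the line TT2 or its mutants: wild type (WT TT2), a line lacking G9a and carrying a catalytically mutant G9a transgene (G9a CM), and a line labelled as lacking both G9a and its partner GLP (the library labelled G9a/GLP DKO). 3 came from the line J1 or its mutants: wild type (WT J1), a line lacking the de novo DNA methyltransferases (Dnmt3a/3b DKO) and a line that also lacks the maintenance enzyme (Dnmt1/3a/3b TKO). The other 4 were TT2 cells given the G9a and GLP inhibitor UNC0638 and collected on day 2, 4 or 14, and their vehicle control (the inhibitor control). The dose is 250 nM in the sample titles and 250 µM in the treatment protocol, and the labels do not say whether the day 14 cells were treated throughout. Total counts per library were 25609600 in WT TT2, 16530318 in G9a CM, 11436808 in the library labelled G9a/GLP DKO, 16405518 in WT J1, 16159575 in Dnmt3a/3b DKO and 17595050 in Dnmt1/3a/3b TKO. They were 14760140 in the inhibitor control and 18212923, 18053117 and 15886733 on days 2, 4 and 14. No group had a replicate, so no test between conditions was possible, and every interval given here is a 95% exact counting interval that covers counting error only. Higher and lower refer to the libraries, and a gene is counted as higher or lower only where it passed the size rule.

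The targeted genes were read first in every library. Ehmt2, which encodes G9a (ENSMUSG00000013787.15, chromosome 17, 34898463 to 34914073, GRCm38), stood at 14.6 CPM in WT TT2, 27.8 in G9a CM and 17.9 in the library labelled G9a/GLP DKO. It was therefore not lower in the library labelled G9a/GLP DKO. Its counts cover the whole gene, the deleted part is not given in the sources used here, and transcripts of the G9a CM transgene can count towards it, so its level cannot check either label. Ehmt1, which encodes GLP (ENSMUSG00000036893.17, chromosome 2, 24790769 to 24919643), was 4.81-fold lower (interval 3.92 to 5.97) in the library labelled G9a/GLP DKO than in WT TT2, at 7.95 against 38.3 CPM, and stood at 47.9 CPM in G9a CM. Dnmt3b (ENSMUSG00000027478.15, chromosome 2, 153649411 to 153687730) was 8.83-fold lower (interval 6.59 to 12.1) in Dnmt3a/3b DKO than in WT J1 and 10.0-fold lower (interval 7.44 to 13.8) in Dnmt1/3a/3b TKO. Dnmt3a (ENSMUSG00000020661.15, chromosome 12, 3801559 to 3914443) was 4.04-fold lower (interval 3.10 to 5.32) and 3.65-fold lower (interval 2.85 to 4.71) in these libraries by counts, but by deposited TPM its log2 difference was 0.10 in Dnmt3a/3b DKO. Dnmt1 (ENSMUSG00000004099.16, chromosome 9, 20907206 to 20959888) was 7.34-fold lower (interval 6.03 to 9.02) in Dnmt1/3a/3b TKO than in WT J1 and stood at 62.5 against 46.6 CPM in Dnmt3a/3b DKO and WT J1. In the inhibitor control and on days 2, 4 and 14, Ehmt2 stood at 77.2, 60.0, 78.9 and 66.6 CPM and Ehmt1 at 50.9, 59.6, 46.4 and 45.5 CPM.

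The library labelled G9a/GLP DKO was compared with WT TT2 to ask which genes differ in a line labelled as lacking both H3K9 methyltransferases. Genes of X-linked families and of the 2-cell embryo were higher. Magea8, a member of the X-linked MAGE-A family normally read in testis (chromosome X, 154985775 to 154995850), was 1640-fold higher (interval 560.4 to 7956), at 193 against 0.118 CPM. Pramel6, a PRAME-family gene of the early embryo, stood at 271 against 1.46 CPM (186-fold higher), Xlr3c at 84.0 against 0.786 CPM (107-fold higher) and Zscan4d, a marker of the 2-cell stage, at 42.8 against 0.629 CPM (68.0-fold higher). Esr1, the estrogen receptor alpha gene, had 0 counts in WT TT2 and was at least 346-fold higher, at 40.8 CPM. Of the lists, 9 of 10 measured Mage genes were higher, with a median log2 difference of 4.11 (7.14 with counts under the floor set to it), 22 of 23 2-cell-stage genes (2.74, 5.66 at the floor), 9 of 13 Xlr genes (2.71, 2.91 at the floor) and 9 of 14 Rhox homeobox genes (1.32, 3.29 at the floor). Each median lay at percentile 100.0 of the random lists, which may be too extreme because members of these families share reads and random members do not. Members under 1 CPM in WT TT2 can be counted only when higher, and 1, 3, 7 and 6 members of these lists reached that level there, so the shares partly follow from the minimum. Over all 24, 31, 22 and 42 listed members with no minimum, the counting interval of the ratio lay above 1 for 9, 27, 11 and 11 and below 1 for 1, 0, 0 and 0. In the germline list the members went both ways, with 6 higher and 5 lower of 34: the testis ribosomal protein gene Rpl10l stood at 211 against 21.4 CPM and the meiotic gene Tex11 at 2.28 against 27.4 CPM.

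Among imprinted genes, 12 of 45 were higher and 5 lower in the library labelled G9a/GLP DKO than in WT TT2. The maternally expressed noncoding RNAs Meg3 and Rian were 51.7-fold higher (interval 31.9 to 89.5) and 26.9-fold higher (interval 18.9 to 39.5), and Kcnq1ot1, the paternally expressed antisense RNA of the Kcnq1 domain, was 5.91-fold higher, while Sgce was 6.28-fold lower. Trophoblast markers were higher for 6 of 11 members, with the transcription factor Gata3 at 7.40 against 0.865 CPM and the keratin Krt19 at 9.21 against 1.46 CPM. The same list had 5 of 10 members higher in G9a CM (median 1.01) and 8 of 11 in the inhibitor control (median 1.58), which is also wild-type TT2. WT TT2 thus lay low for it against that wild-type library, but not against WT J1, which had 2 higher and 3 lower of 9 (median -0.39). Of the naive pluripotency genes 3 of 23 were higher and 0 lower, among them Fgf4 at 129 against 48.9 CPM and Pou5f1 at 26.8 against 12.5 CPM. The median of the list was 0.06 at percentile 88.9, within the range of the random lists. Pou5f1 was far higher in the inhibitor control than in either library, as given below. Genes lower in the library labelled G9a/GLP DKO included Ccnd2, which encodes the G1 cyclin D2 (0.866 against 37.8 CPM, 43.6-fold lower, interval 24.3 to 87.7), Bdh2 (18.5-fold lower), the stress-response gene Nupr1 (15.6-fold lower), the transcriptional repressor gene Bhlhe41 (28.9-fold lower), the acyl-CoA thioesterase gene Acot1 (14.6-fold lower) and Hmgn3 (13.2-fold lower). The Atf4 and amino acid response list had 9 of 22 members lower and 0 higher, with a median of -0.81 at percentile 0, and examples Chac1 (5.82 against 58.2 CPM), Atf3 (0.708 against 11.4 CPM) and Ddit3 (4.80 against 38.3 CPM). In the sterol biosynthesis list 3 of 20 were lower and 0 higher, with a median of -0.48 at percentile 0.29. In all, 1370 genes were higher and 995 lower of 14027 measured, so 57.9% of calls were higher, against 70.0% when scaled by total count and 70.2% by deposited TPM. Against WT J1 as another control, a choice made after seeing the data, 933 of the 1370 genes were also higher and 527 of the 995 also lower.

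**Figure D1:**
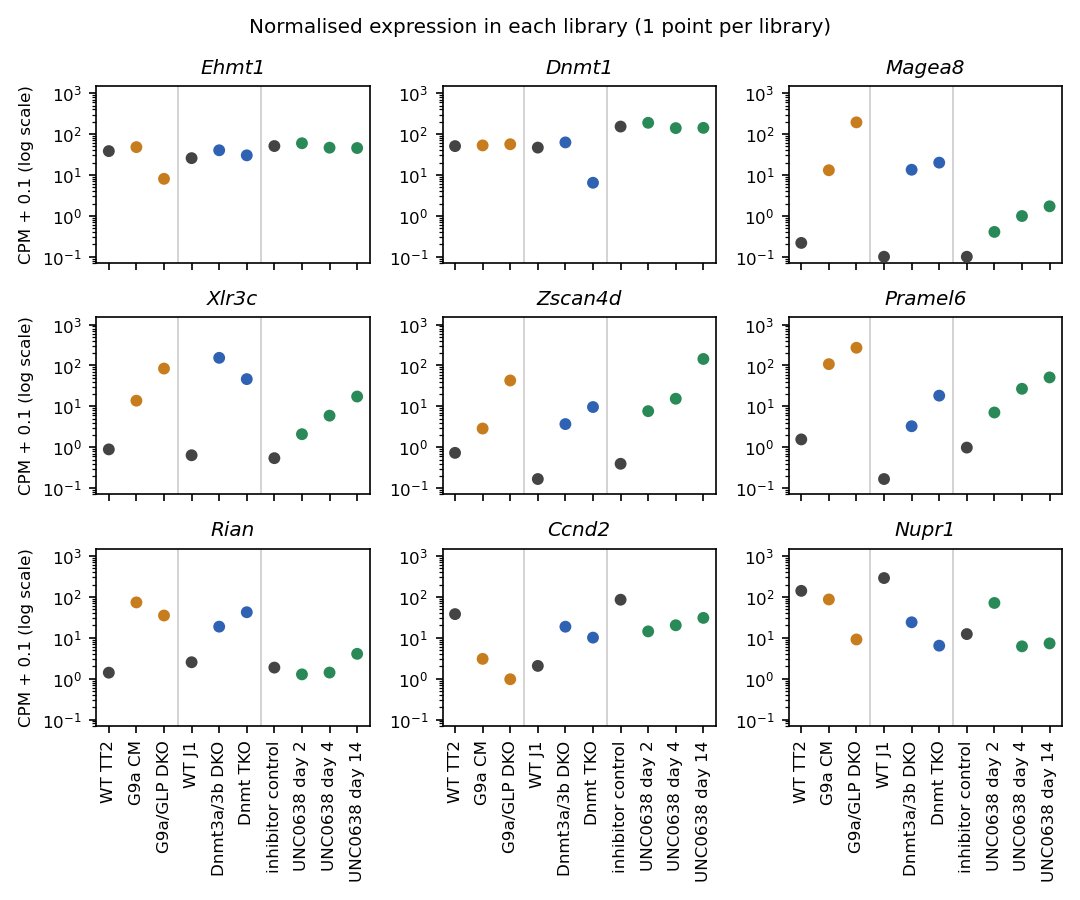
Normalised expression of 9 genes in the 10 libraries, 1 point per library, as CPM + 0.1 on a log axis, with grey lines between the TT2, J1 and inhibitor sets. Magea8, Xlr3c, Zscan4d and Pramel6 lie above the wild-type or vehicle library of the same set in all 4 mutant libraries and on days 2, 4 and 14, with Magea8 at 193 CPM in the library labelled G9a/GLP DKO and Zscan4d at 144 CPM on day 14.

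G9a CM was compared with WT TT2 to ask what differs when G9a is present without its catalytic activity. Genes far above WT TT2 included members of the PRAME, Xlr and imprinted groups, among others. Pramel6 stood at 108 against 1.46 CPM (74.0-fold higher, interval 53.5 to 106), Pramel7 at 31.9 against 1.53 CPM, Elobl at 49.3 against 1.02 CPM and Xlr5a at 20.1 against 0.236 CPM, and the growth-arrest gene Gadd45g was 37.4-fold higher (interval 27.6 to 52.0). Slc5a4b was 18.96-fold higher and Klb, which encodes the co-receptor beta-klotho, 27.2-fold higher. Pagr1a was 44.9-fold higher, but its count is uncertain, with a posterior SD of 22.6% of it in G9a CM. Rian and Meg3 were 56.3-fold higher (interval 39.9 to 82.1) and 68.1-fold higher (interval 42.3 to 118), and H19, the maternally expressed noncoding RNA next to Igf2, was 7.91-fold higher. Of 9 measured Mage genes 7 were higher (median 1.90, 4.61 at the floor), of 12 2-cell-stage genes 9 (median 1.13, 3.12 at the floor), of 12 Xlr genes 8 (median 1.47) and of 11 Rhox genes 6 (median 1.00). Each median lay at percentile 100.0, with the same limit for families that share reads, and these shares too partly follow from the minimum of 1 CPM. Over all 24, 31, 22 and 42 listed members with no minimum, the counting interval lay above 1 for 9, 20, 9 and 12 and below 1 for 1, 0, 0 and 1. Magea8 stood at 12.96 against 0.118 CPM and Zscan4a at 4.83 against 0.433 CPM.

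Other groups differed between G9a CM and WT TT2. Of 47 measured replication-dependent histone genes 18 were higher and 2 lower, with a median of 0.80 at percentile 100.0, although such near-identical copies are uncertain one by one. The meiotic cohesin gene Smc1b was 14.4-fold higher (interval 12.0 to 17.4), in a germline list with 8 higher and 2 lower of 36. Interferon-stimulated genes had 5 of 13 members higher and 0 lower, with a median of 0.80, among them the nucleic acid sensor gene Zbp1 at 21.4 against 4.56 CPM. Of the formative and primed pluripotency genes 4 of 9 were higher, with Fgf5 at 3.48 against 0.826 CPM. Dnmt3b, Dnmt3a and Dnmt3l, the cofactor of both enzymes, were 2.96-fold higher, 2.69-fold higher and 4.72-fold higher. Genes lower in G9a CM included Slc24a5 (16.9-fold lower), the apoptosis protease gene Casp8 (25.3-fold lower), Acot1 (12.0-fold lower), Ccnd2 (12.8-fold lower, interval 9.64 to 17.4), Hmgn3 (8.64-fold lower) and Mlf1 (7.08-fold lower). The Atf4 list had 6 of 22 members lower (median -0.41), and the mitochondrially encoded genes a median of -0.56 at percentile 0.29. Across all genes 729 were higher and 685 lower of 13504 measured, so 51.6% of calls were higher, against 65.0% by deposited TPM. Without chromosomes 1, 8, 11 and Y, a choice made after seeing the data, the count of lower genes was 400.

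The libraries of both G9a lines were set side by side to ask how far the line without catalytic activity and the line labelled as lacking both proteins go together. Of genes measured in both comparisons, 417 were higher and 369 lower in both, where independent lists would share 53.4 and 51.5, and 5 went opposite ways. Both comparisons use the WT TT2 library, and part of that excess can come from it. Unchanged libraries simulated against the shared control, which carry counting error only and so do not measure that part, gave 0 genes in both directions. Their covariance across genes was 0.0084, against 0.367 observed. With the inhibitor control in the G9a CM comparison, so that no library was shared, 435 genes were higher in both, against 217.9 for independent lists, but 176 were lower in both, against 214.4, with the second lists grown from 694 and 685 to 2752 and 3015 genes. In these lists 383 genes went opposite ways, and the correlation across genes was 0.069. With the shared control it was 0.678, where the simulated unchanged libraries gave 0.392. With WT J1 there, a choice made after seeing the data, 453 and 342 were shared, against 171.1 and 147.0, and 196 went opposite ways. The Mage genes were higher in the library labelled G9a/GLP DKO than in G9a CM for 9 of 11 members (median 1.74) and the 2-cell-stage genes for 19 of 23 (median 2.04). Magea8 was 14.9-fold higher and Zscan4d 15.5-fold higher (interval 11.5 to 21.3). The genes furthest above G9a CM were Ddx3y, Eif2s3y and Uty, all on the Y chromosome, and Esr1. Ddx3y stood at 78.3 against 0.0589 CPM and Esr1 at 40.8 against 0.118 CPM. Interferon-stimulated genes were lower in the library labelled G9a/GLP DKO for 4 of 13 members (median -0.84), histone genes for 11 of 48 (median -0.57) and Atf4-list genes for 5 of 21 (median -0.64). Nupr1 was 9.62-fold lower, Gna14 9.87-fold lower and Enpp2, which encodes autotaxin, 12.8-fold lower. In all, 925 genes were higher and 414 lower of 13869 measured.

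Dnmt3a/3b DKO was compared with WT J1 to ask which genes differ without de novo DNA methylation. The Xlr genes lay furthest above the wild type, and 10 of 13 measured members were higher with a median of 4.84 (7.11 at the floor). Xlr3c stood at 154 against 0.537 CPM (286-fold higher, interval 145 to 664) and Xlr4a at 45.6 against 0.134 CPM. Aass, which encodes an enzyme of lysine degradation (chromosome 6, 23072173 to 23132986), was 149-fold higher (interval 105 to 219.8), and Dppa3, an oocyte and primordial germ cell gene, 61.3-fold higher (interval 48.5 to 78.7). All 11 of 11 measured Rhox genes were higher (median 1.88), with Rhox6 at 55.6 against 1.88 CPM. Higher members were 5 of 7 in the Mage list (median 1.76), 7 of 9 in the 2-cell-stage list (median 1.71) and 8 of 11 in the trophoblast list (median 1.46). Of the Mage, Rhox, Xlr and 2-cell-stage lists only 2, 5, 3 and 2 members reached 1 CPM in WT J1, and over all 24, 42, 22 and 31 members with no minimum the counting interval lay above 1 for 9, 15, 10 and 11 and below 1 for 0, 0, 1 and 0. Magea8 had 0 counts in WT J1 and was at least 66.2-fold higher. In the germline list 12 of 35 were higher and 4 lower, with Fkbp6, a piRNA-pathway gene, at 78.9 against 1.95 CPM. Its median was 0.21 at percentile 88.9, and with no minimum the interval lay above 1 for 17 and below 1 for 13 of 41 members. Imprinted genes had 13 higher and 4 lower of 45, with H19 50.5-fold higher (interval 28.7 to 98.1) and Peg3 9.75-fold higher (interval 8.05 to 11.9).

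Genes lower in Dnmt3a/3b DKO than in WT J1 included Ripply3 (47.4-fold lower), Ulk4 (44.4-fold lower), the cholesterol exporter gene Abca1 (20.8-fold lower), the cation channel gene Trpm1 (18.4-fold lower), the transcription factor gene Pou4f2 (16.2-fold lower) and Cpe (15.8-fold lower). Trpm1 and Pou4f2 were also far lower in WT TT2 than in WT J1, as given below. Of the Atf4 list 9 of 21 members were lower and 0 higher (median -0.89), with Nupr1 12.1-fold lower and Chac1 7.23-fold lower. In the naive pluripotency list 2 of 23 were higher and 6 lower, the lower ones led by Klf5 (24.2 against 122 CPM) and Tbx3 (4.78 against 23.4 CPM). The median of this list was nevertheless 0.13 at percentile 91.2. With no minimum its counting interval lay above 1 for 12 members and below 1 for 8, so the list as a whole was not lower. The formative and primed genes Cldn6, Fgf15 and Otx2 were 5.49-fold higher, 5.88-fold higher and 5.36-fold higher, and the neural transcription factor gene Pax6 stood at 24.4 against 0.269 CPM. Sterol biosynthesis genes had 5 of 19 members higher and 0 lower (median 0.77), and ribosomal protein genes a median of -0.50 at percentile 0.07. Against WT TT2, WT J1 itself had medians of -0.94 and 0.57 for these 2 lists, so WT TT2 differed from WT J1 in the same directions. Altogether 1269 genes were higher and 1359 lower of 13743 measured, so 48.3% of calls were higher, against 63.7% scaled by total count and 74.5% by deposited TPM. When WT TT2 was also used as control, a choice made after seeing the data, 353 of the 1269 genes were higher and 222 of the 1359 lower against both wild types.

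Dnmt1/3a/3b TKO was compared with WT J1 to ask the same with maintenance methylation lost as well. The Xlr genes again had 10 of 13 members higher (median 3.46, 5.74 at the floor), with Xlr3a 220.1-fold higher (interval 101 to 601). Calcoco2, an autophagy receptor gene of the 2-cell-stage list, stood at 904 against 15.9 CPM (56.8-fold higher, interval 49.98 to 64.9). Mgl2, a macrophage lectin gene, had 0 counts in WT J1 and was at least 204-fold higher. All 12 of 12 Rhox genes (median 1.98), 7 of 9 Mage genes (median 1.37), 8 of 9 2-cell-stage genes (median 2.35) and 10 of 12 trophoblast markers (median 1.38) were higher. With no minimum the counting interval lay above 1 for 14 of 42 Rhox, 10 of 24 Mage, 9 of 31 2-cell-stage and 10 of 22 Xlr members, and below 1 for 0. The germline list had 14 higher and 2 lower of 36, with Fkbp6 51.8-fold higher (interval 35.9 to 77.6) and Asz1, a piRNA-pathway gene with 0 counts in WT J1, at least 124-fold higher. Imprinted genes had 15 higher and 6 lower of 48, with H19 at 39.9 against 0.805 CPM and Rian at 42.0 against 2.42 CPM. The most negative differences were those of Nupr1 (6.30 against 288 CPM, 45.8-fold lower, interval 38.0 to 55.6), Trpm1 (29.5-fold lower), Ripply3 (26.4-fold lower), Chac1 (22.5-fold lower), Bhlhe41 (39.6-fold lower) and Pou4f2 (19.9-fold lower). The Atf4 list had 11 of 20 members lower and 0 higher (median -1.35, percentile 0), with Atf4 itself at 27.1 against 187 CPM. Of ribosomal protein genes 12 of 84 were lower and 2 higher, with a median of -0.56, and of sterol biosynthesis genes 0 were higher and 1 lower of 19 (median 0.36). In total 1534 genes were higher and 1482 lower of 13924 measured, so 50.9% of calls were higher, against 65.5% scaled by total count and 74.5% by deposited TPM. Against both wild types 491 of the 1534 genes were higher and 241 of the 1482 lower.

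Both Dnmt mutants shared 879 higher and 981 lower genes, where independent lists would share 126.6 and 148.9, and 0 genes went opposite ways. WT J1 serves as control of both, and part of that excess can come from it. Simulated unchanged libraries, which carry counting error only and so do not measure that part, gave 0 genes in both directions and a covariance of 0.014, against 0.688 observed. With WT TT2 as control of the second comparison, a choice made after seeing the data, the counts were 332 and 180, against 95.8 and 68.3, and 112 genes went opposite ways. Compared directly, Dnmt1/3a/3b TKO had 241 genes higher and 182 lower than Dnmt3a/3b DKO of 13461 measured. Without chromosomes 1, 8, 11 and Y, a choice made after seeing the data, 161 were higher and 159 lower. By deposited TPM 281 were higher and 140 lower. The difference between these libraries also went with gene length, with a Spearman correlation across genes of -0.344, the strongest of the 11 comparisons. How far gene length set these counts was not tested. The early embryo genes Pramel6 (5.74-fold higher, interval 4.29 to 7.82), Pramel7 (5.23-fold higher) and Calcoco2 (3.68-fold higher, interval 3.56 to 3.81) led the higher ones, followed by Them5 (4.49-fold higher), and 3 of 9 2-cell-stage genes were higher. Dnmt1 was 9.84-fold lower (interval 8.12 to 12.0), Eif4g3 6.86-fold lower, the hypoxia-responsive repressor gene Bhlhe40 6.73-fold lower and D1Pas1 5.40-fold lower. The formative and primed genes had 4 of 9 members lower (median -0.80), with Sox11 at 2.90 against 13.2 CPM, and 4 of 13 Xlr genes were lower, with Xlr3c at 46.3 against 154 CPM.

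UNC0638 was followed over time against the inhibitor control to ask which genes differ when G9a and GLP are inhibited in wild-type cells. The labels do not say when the single control was collected, so differences from it can also hold time in culture. Among genes with at least 10 CPM, those furthest above the control on day 2 included stress and hypoxia genes. Ddit3, the gene of the stress transcription factor CHOP, was 9.63-fold higher (interval 7.13 to 13.3), at 32.5 against 3.38 CPM, and Bhlhe40 was 6.33-fold higher (interval 5.13 to 7.88). Nupr1 was 5.81-fold higher, the mitophagy receptor gene Bnip3 5.10-fold higher, Ddit4, which encodes an inhibitor of mTORC1, 4.96-fold higher, and the thioredoxin-binding gene Txnip 4.65-fold higher. Of the Atf4 list 6 of 22 members were higher and 0 lower (median 0.52, percentile 100.0). A list of hypoxia-inducible genes added after these values were seen had 10 of 23 members higher and 0 lower (median 0.84), with Ndrg1 at 72.6 against 19.02 CPM. The 2-cell-stage genes were higher for 11 of 14 members (median 1.502, 3.20 at the floor), led by Zscan4d (25.6-fold higher, interval 9.81 to 95.3), and 10 of 33 germline genes were higher, led by the germ cell transcription factor gene Sohlh2 (4.92-fold higher). Genes lower on day 2 included Wrnip1 (11.1-fold lower), Krt8 (10.9-fold lower), the RNA-binding protein genes Ybx1 (8.26-fold lower, interval 7.997 to 8.54) and Pcbp1 (7.13-fold lower), Riox1 (7.33-fold lower) and the glutathione synthesis gene Gclm (6.35-fold lower). Growth and cell cycle genes had 6 of 19 members lower and 0 higher (median -0.53), with Ccnd2 at 14.2 against 84.97 CPM and Myc at 21.6 against 85.6 CPM. Dnmt3b stood at 246 against 511 CPM. On this day 415 genes were higher and 245 lower of 13294 measured, so 62.9% of calls were higher, against 51.6% with DESeq2 size factors, 83.1% scaled by total count and 81.5% by deposited TPM.

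On day 4 of UNC0638 Pramel6 (26.8 against 0.881 CPM, 30.4-fold higher, interval 17.2 to 59.3) and Zscan4d (15.3 against 0.294 CPM, 52.0-fold higher, interval 20.1 to 192) led the higher genes. They were followed by Mgl2 (13.3-fold higher), the RNA export factor gene Nxf3 (9.61-fold higher), Nckap1l (8.37-fold higher), Sohlh2 (5.495-fold higher), the lymphocyte receptor gene Cd6 (5.72-fold higher) and the laminin gene Lama3 (5.19-fold higher). The 2-cell-stage list had 14 of 16 members higher (median 1.37, 3.08 at the floor), the Xlr list 9 of 12 (median 1.38) and the germline list 10 of 31 (median 0.48). With no minimum the counting interval lay above 1 for 20 of 31, 10 of 22 and 17 of 41 listed members and below 1 for 0, 1 and 3. The simple-epithelial keratin genes Krt8, Krt19 and Krt18 were 13.4-fold lower (interval 10.6 to 17.2), 7.10-fold lower and 5.24-fold lower, and Ccnd2 was 4.23-fold lower (interval 3.75 to 4.79). The trophoblast list, which holds these keratins, had 1 higher and 3 lower of 10 (median -0.49, percentile 0). The Atf4 list lay on the other side of the control from day 2, with 4 of 22 members lower and 0 higher (median -0.57), among them Chac1 (10.9-fold lower, interval 8.38 to 14.4) and Trib3 (2.96-fold lower). The hypoxia-inducible list had 0 of 22 members higher and 0 lower. Counts were 256 higher and 88 lower of 13112 measured.

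By day 14 the 2-cell-stage genes lay far above the control, with 24 of 26 measured members higher and a median of 3.02 (5.12 at the floor). Only 2 members reached 1 CPM in the control, so which members were measured follows from the change itself. Over all 31 listed members with no minimum, the counting interval lay above 1 for 29 and below 1 for 0, against 17 and 1 on day 2. Zscan4d (chromosome 7, 11161643 to 11166148) stood at 144 against 0.294 CPM (491-fold higher, interval 191 to 1802), Zscan4c at 93.6 against 0.588 CPM and Zscan4f at 55.5 against 0.294 CPM. The deubiquitinase genes Usp17lb, Usp17le, Usp17la and Usp17lc were 364-fold higher (interval 101 to 3014), 88.8-fold higher (interval 30.1 to 433), 67.0-fold higher (interval 25.9 to 248) and 189-fold higher (interval 33.6 to 7501), where the last rests on 1 control count, and Pramel6 was 57.8-fold higher (interval 32.9 to 112). Members of the Zscan4 and Usp17l families are near-identical, so single genes are uncertain. The Xlr list had 9 of 12 members higher (median 2.09), the germline list 9 of 32 (median 0.46) with the meiosis gene Stra8 at 47.7 against 8.30 CPM, and the Mage list 2 of 5. The endoderm genes Gata4 and Sox17 stood at 5.55 against 1.32 CPM and 2.00 against 0.294 CPM, in a list with 4 of 15 higher. Lower genes included Pagr1a (49.5-fold lower, with a posterior SD of 74.8% of the control count), the netrin gene Ntn1 (7.24-fold lower, interval 4.997 to 10.8), Chac1 (4.15-fold lower, interval 3.46 to 5.002), Ap1m2 (3.19-fold lower) and the Hedgehog target gene Gli1 (3.12-fold lower). Of imprinted genes 1 was higher and 3 were lower of 44. In all 387 genes were higher and 71 lower of 13269 measured.

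Across the inhibitor time points, days 2 and 4 shared 141 higher genes, days 2 and 14 shared 146, and days 4 and 14 shared 181, where independent lists would share 6.4, 7.9 and 5.3. Lower genes shared numbered 22, 18 and 22, against 1.7, 1.3 and 0.5. The time points share the inhibitor control, and part of these excesses can come from it. Unchanged libraries simulated against it, which carry counting error only and so do not measure that part, gave at most 0.01 shared genes on average. Their covariance was 0.0141 to 0.0142, against 0.0741, 0.0992 and 0.118 observed. With WT TT2 as control of the later time point, so that no library was shared, 140, 160 and 145 higher genes were shared, against 107.9, 111.8 and 69.9 for independent lists, and 29, 21 and 17 lower genes, against 49.2, 48.8 and 16.7. The values for independent lists rose because the later time point then had 3541, 3649 and 3666 higher genes, in place of 218, 267 and 285, so the smaller excess does not show that the sharing came from the common control. Then 182, 193 and 35 genes went opposite ways, and the correlations across genes were -0.089, -0.051 and 0.118. With the shared control they were 0.399, 0.447 and 0.692, where the simulated unchanged libraries gave 0.594, 0.582 and 0.565, so those of day 2 lay below the simulated values. WT TT2 itself differed from the inhibitor control at 3448 and 3009 genes.

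The G9a and Dnmt mutants and the inhibitor were set side by side to ask which genes lie above the control in each, first in pairs of comparisons that share no library. The library labelled G9a/GLP DKO and Dnmt1/3a/3b TKO shared 432 higher and 269 lower genes, against 115.2 and 92.9 for independent lists, and 76 genes went opposite ways. G9a CM and Dnmt1/3a/3b TKO shared 289 and 172, against 68.0 and 65.1, with 70 opposite. The library labelled G9a/GLP DKO shared 227 higher and 23 lower genes with day 14 of UNC0638, against 24.4 and 4.3, with 7 opposite. G9a CM shared 126 and 12 with day 14, against 11.8 and 3.1, with 17 opposite, and Dnmt1/3a/3b TKO shared 138 and 18, against 25.1 and 5.9, with 25 opposite, so for these libraries more genes went opposite ways than were lower in both. In all 4 mutants 155 genes were higher than in the own wild type. These comparisons share WT TT2 or WT J1 within each pair of mutants. The genes higher in both G9a lines and those higher in both Dnmt mutants, taken as independent lists, would share 21.9. Of the 155 genes 128 were measured on day 14 and 57 were higher then, against 2.3 for independent lists. A gene under 1 CPM in the inhibitor control was measured only if it reached that level on day 14, and could be counted only as higher. The 2.3 takes the rate over all measured genes, so part of the excess can follow from this minimum. Higher than in both wild types in all 4 mutants were 93 genes, a count whose comparisons share both controls and for which no chance value was computed. Among the 57, named after their values were seen, were Magea5, Magea8, Pramel6, Pramel7, Nlrp4c, Asz1, Rhox2a, Xlr3b, Xlr3c, Zscan4a, Zscan4c, Zscan4d and Zscan4f.

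**Figure D2:**
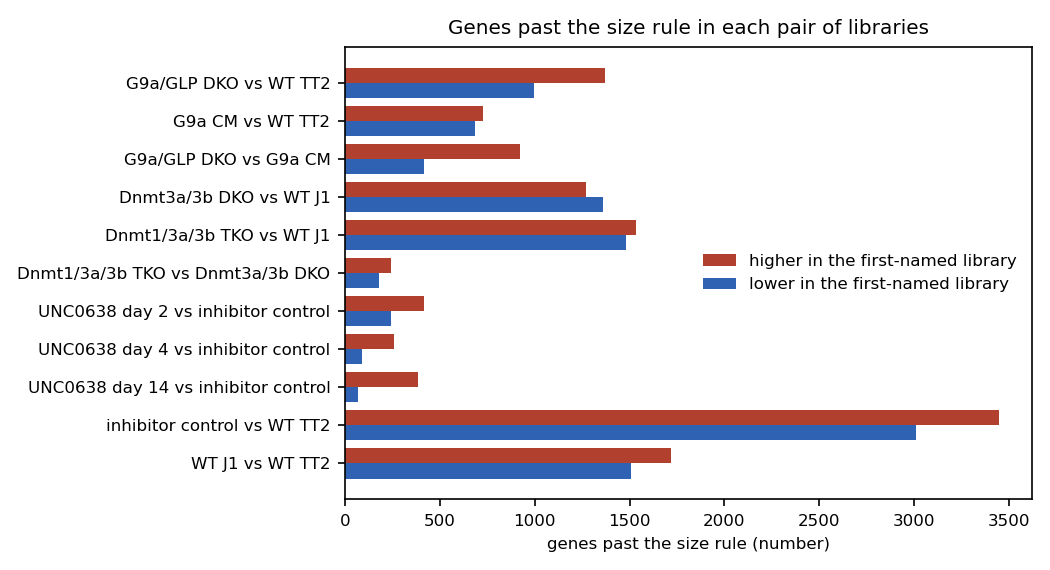
Number of genes past the size rule, higher (red) and lower (blue) in the first-named library, for the 11 pairs of libraries compared. The bars run from 71 lower genes on day 14 of UNC0638 to 3448 higher genes in the inhibitor control against WT TT2.

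The wild-type and vehicle libraries were compared with each other as a background for the mutants. The inhibitor control and WT TT2, both wild-type TT2 by label, differed at 3448 higher and 3009 lower genes of 13667 measured, more than any mutant did from its control, and 53.4% of calls were higher, against 65.2% by deposited TPM. Lrch4 had 0 counts in WT TT2 and was at least 901-fold higher in the inhibitor control, and Raver1, the lactate transporter gene Slc16a3 and Hmga1 were 238-fold higher, 134-fold higher and 82.7-fold higher. Slc24a5 and Exosc6 had 0 counts in the inhibitor control and were at least 208-fold lower and at least 62.1-fold lower, and Dqx1 and Nsmce4a were 18.6-fold lower and 13.8-fold lower. Ribosomal protein genes were lower for 44 of 84 members (median -1.04) and mitochondrially encoded genes for 10 of 13 (median -1.27), while growth and cell cycle genes were higher for 10 of 19 (median 1.15). The pluripotency factor gene Pou5f1 stood at 455 against 12.5 CPM. Set against the inhibitor control in place of WT TT2, the library labelled G9a/GLP DKO had 3286 higher and 3473 lower genes and G9a CM 2808 and 3394. Correlations across genes, which are not independent replicates, were 0.981 to 0.991 within the 4 inhibitor libraries, 0.900 to 0.985 within the other 6 and 0.771 to 0.883 between these sets.

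WT J1 and WT TT2, which differ in strain, had 1716 genes higher and 1505 lower in WT J1 of 13735 measured. The Y-linked genes Eif2s3y and Ddx3y were 136-fold higher and 65.8-fold higher in WT J1, and Pou4f2 and Trpm1 were 299.7-fold higher and 78.1-fold higher. Dppa3 was 115-fold lower (interval 91.2 to 148), Rpl29 69.6-fold lower, Ndufs5 60.8-fold lower and Xlr3a 143-fold lower. Of the Rhox genes 4 of 6 were lower in WT J1 (median -1.92), of the Xlr genes 4 of 7 (median -1.90) and of the sterol biosynthesis genes 7 of 20 (median -0.94), while 26 of 84 ribosomal protein genes were higher and 3 lower. Dppa3, Rhox6, Xlr3a and Calcoco2, which lay above WT J1 in both Dnmt mutants, were also above it in WT TT2, at 549, 57.2, 57.4 and 76.5 CPM. Likewise Pou4f2, Trpm1 and the median of the ribosomal protein genes, which lay below WT J1 in both Dnmt mutants, were also below it in WT TT2. Naive pluripotency genes had 8 higher and 1 lower of 23 in WT J1 (median 0.78, percentile 100.0). Formative and primed genes had 1 higher and 3 lower of 8 (median -0.72, percentile 1.69). Higher calls made up 53.3%, against 43.2% scaled by total count and 29.5% by deposited TPM.

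Differences were also summarised by chromosome, over genes with a CPM of at least 10 in either library and relative to the median over all autosomal genes. Against WT TT2, chromosome 1 genes had a median shift of -0.54 in the library labelled G9a/GLP DKO and -0.53 in G9a CM. Chromosome 8 genes had a median shift of -0.45 in G9a CM against WT TT2 and 0.52 in the library labelled G9a/GLP DKO against G9a CM. Chromosome 11 genes had a median shift of 0.64 in Dnmt1/3a/3b TKO against WT J1 and 0.41 against Dnmt3a/3b DKO, and of 0.20 in Dnmt3a/3b DKO against WT J1. Against WT TT2 it had -0.60 in WT J1, -0.37 in Dnmt3a/3b DKO and 0.05 in Dnmt1/3a/3b TKO. The X chromosome had medians of 0.01 and -0.04 in the library labelled G9a/GLP DKO and G9a CM against WT TT2. The Y-linked gene Ddx3y stood at 1.34 CPM in WT TT2, 0.0589 in G9a CM and 78.3 in the library labelled G9a/GLP DKO, and at 88.0 CPM in WT J1, 77.6 in Dnmt3a/3b DKO and 152.0 in Dnmt1/3a/3b TKO. In the inhibitor control and on days 2, 4 and 14 Ddx3y stood at 0.294, 1.02, 1.72 and 3.36 CPM. Zfy1, Kdm5d, Uty and Eif2s3y, the other Y-linked genes with at least 5 CPM in any library, were likewise higher in the library labelled G9a/GLP DKO than in WT TT2 and G9a CM. Every difference of that library from these is therefore between lines that also differ in Y-linked expression.

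**Figure D3:**
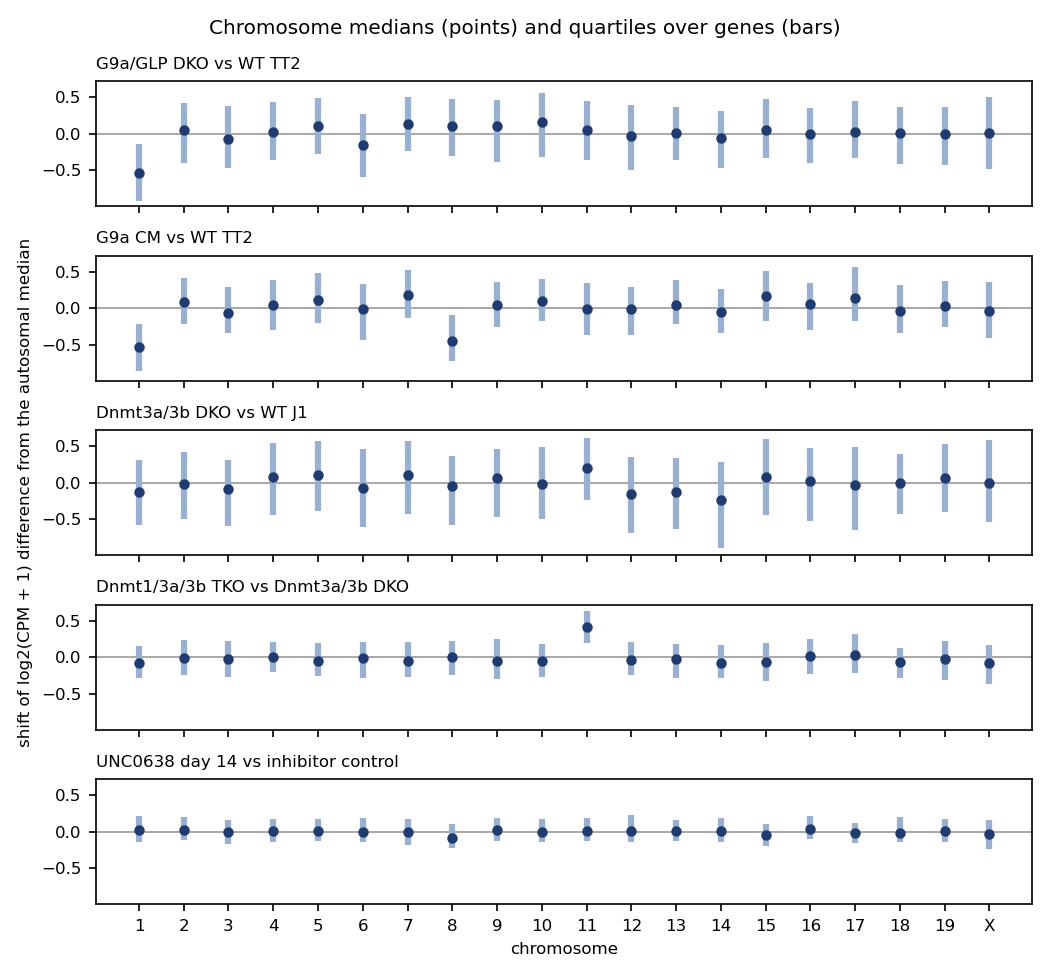
Median (points) and quartiles over genes (bars) of the log2(CPM + 1) difference per chromosome, minus the median over all autosomal genes, in 5 comparisons. Chromosome 1 lies at -0.54 and -0.53 in the G9a lines, chromosome 8 at -0.45 in G9a CM and chromosome 11 at 0.41 between the Dnmt mutants.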

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

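No test in this part was chosen after its result was seen. Chac1, which encodes a glutathione-degrading enzyme, lay on opposite sides of the inhibitor control at different times of UNC0638 treatment. Its log2 difference was 1.53 on day 2, -3.14 on day 4 and -1.95 on day 14, with 119.8, 3.74 and 9.81 CPM against 40.8 CPM in the control. Ddit3, the gene of the stress transcription factor CHOP, had a difference of 2.94 on day 2 and -1.001 on day 4. With 1 library per time point the differences between time points were not tested.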

How the results depend on the processing

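No paired analysis was possible because each group had 1 library. For the same reason leaving out each replicate, the replicate block and the DESeq2 Wald test were not run. The tests with WT J1 as control of the G9a lines, with WT TT2 as control of the Dnmt mutants, without chromosomes 1, 8, 11 and Y, and of list members by counting interval were chosen after the results were seen. Leaving out the minimum of 1 CPM could move nothing, since at a pseudocount of 1 CPM the size rule already needs that level, and it is not counted here. Of 172 counts of genes past the size rule under the other alternatives, 105 stayed within 1.5 times of the value reported and 67 did not. Among these counts, another control moved 4 of 4 with the inhibitor control, 4 of 4 with WT J1 and 7 of 10 with WT TT2. Of 582 list medians 41 moved, but these were recomputed only with DESeq2 size factors and deposited TPM, never with another control. Of 220 chromosome medians, recomputed only at 1 CPM, 8 moved, and of 12 overlaps, recomputed only with another control, 3 moved. Of 616 counts of list members 465 moved when counted by the interval alone, which by its construction drops the size threshold and the minimum. Of 7422 log2 differences of named genes 6758 stayed on the same side of the rule, 497 no longer passed it, 165 newly passed it and 2 reversed. Direction was compared only for genes that passed the rule in the main setting. Another pseudocount or minimum cannot reverse it, and no other control was tried for these genes.

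By deposited TPM the reversed differences were Dnmt3a in Dnmt3a/3b DKO against WT J1, at 0.10, and the neural gene Map2 in the inhibitor control against WT TT2, at 0.11. The cause was not tested. Scaling by total count shifted the median of all genes by 0.14 log2 in the library labelled G9a/GLP DKO, 0.17 in both Dnmt mutants, 0.20 on day 2 and -0.11 in WT J1, and TPM shifted it by 0.14, 0.28, 0.28, 0.22 and -0.29, and by 0.25 in the inhibitor control against WT TT2. Changes under those scalings are relative to these shifts. Scaled by total count, day 2 had 710 higher and 144 lower genes. By TPM there were 1909 higher and 653 lower in Dnmt3a/3b DKO, 725 lower in Dnmt1/3a/3b TKO, 713 higher and 162 lower on day 2, and 970 higher and 2318 lower in WT J1 against WT TT2.

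With a minimum of 5 CPM, which leaves fewer genes, higher genes numbered 817 in the library labelled G9a/GLP DKO, 478 in G9a CM, 584 between them, 158 between the Dnmt mutants, and 241, 111 and 188 on days 2, 4 and 14, with 48 and 47 lower on days 4 and 14. A pseudocount of 0.1 CPM, which by its construction lets low genes pass, gave 1206 higher and 1188 lower in G9a CM, 1553 and 776 in the library labelled G9a/GLP DKO against G9a CM, 606 and 452 between the Dnmt mutants, and 867 and 415, 470 and 282, and 671 and 187 on days 2, 4 and 14. A pseudocount of 5 CPM, which shrinks low genes, gave 472 and 469 in the library labelled G9a/GLP DKO, 270 and 256 in G9a CM, 270 and 148 between them, 516 and 685 in Dnmt3a/3b DKO, 642 and 748 in Dnmt1/3a/3b TKO, 57 and 49 between these, 83 and 122, 45 and 9, and 111 and 18 on days 2, 4 and 14, 1894 lower in the inhibitor control against WT TT2, and 856 and 677 in WT J1 against WT TT2.

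With the inhibitor control in place of WT TT2, the library labelled G9a/GLP DKO had 3286 higher and 3473 lower genes and G9a CM 2808 and 3394. With WT J1 they had 2531 and 2325, and 2155 and 2365. With WT TT2 as control, 868 genes were lower in Dnmt1/3a/3b TKO, and days 2, 4 and 14 had 3681 and 2942, 3578 and 3043, and 3782 and 3006. Without chromosomes 1, 8, 11 and Y, which removes genes, 400 were lower in G9a CM. The G9a lines shared 176 lower genes when the second used the inhibitor control, against 214.4 for independent lists, and the Dnmt mutants 332 higher and 180 lower when the second used WT TT2. The causes of these shifts with the control were not tested. Depth limits genes under the floor of 0.118 to 0.236 CPM, where a difference cannot be seen.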

Other observations

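The tests of chromosomes 1, 8 and 11, of the WT TT2 library, of a preparation difference and of gene length bias were chosen after the results, or values related to them, were seen, and so were the 2 added gene lists. Some gene groups have not been described above. Among p53 targets 1 of 15 was higher and 0 lower in the library labelled G9a/GLP DKO than in WT TT2, the kinase gene Plk2 (45.6 against 14.9 CPM). The median of the list was 0.50 at percentile 99.8. With no minimum the counting interval lay above 1 for 10 and below 1 for 3 of 17 members. In Dnmt1/3a/3b TKO 5 were higher and 2 lower of 16 against WT J1 (median 0.53). Cyclin G1 (Ccng1) stood at 439 against 171 CPM and the apoptosis gene Pmaip1 at 5.31 against 43.5 CPM. WT J1 itself had 1 higher and 4 lower of 15 against WT TT2 (median -0.68), so WT TT2 also lay above WT J1 for this list. In the H3K9 and DNA methylation machinery list, Dnmt3l was higher in all 4 mutants than in the own wild type, at 179.8 and 349 CPM in the library labelled G9a/GLP DKO and G9a CM against 73.8 in WT TT2, and 207 CPM in Dnmt3a/3b DKO and 258 CPM in Dnmt1/3a/3b TKO against 33.7 in WT J1. Neuroectoderm genes had 4 of 8 higher in Dnmt3a/3b DKO (median 0.89) and 3 of 8 in Dnmt1/3a/3b TKO (median 0.89), with the neurofilament gene Nefl at 8.01 against 1.88 CPM and 11.3 against 1.88 CPM.

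The added Pramel and Nlrp4 list of oocyte-type genes had 6 of 9 members higher on day 2 of UNC0638, 8 of 9 on day 4 and 8 of 9 on day 14, and 5 of 8 in Dnmt1/3a/3b TKO against Dnmt3a/3b DKO (median 1.37). The hypoxia-inducible list had 1 of 22 members higher and 0 lower on day 14, with a median of 0.33 at percentile 100.0. With no minimum the counting interval lay above 1 for 11 and below 1 for 7 of 26 members. Against WT J1 the same list had 8 of 24 higher and 0 lower in Dnmt3a/3b DKO (median 0.64), and 2 higher and 2 lower of 24 in Dnmt1/3a/3b TKO (median 0.04). Among fibroblast markers, Col1a1 stood at 4.49 against 0.865 CPM in the library labelled G9a/GLP DKO and WT TT2 and Vim at 69.1 against 25.2 CPM, in a list with 2 higher and 1 lower of 6 (percentile 86.3). In G9a CM against WT TT2 the same list had 3 higher and 0 lower of 6, with a median of 0.69 at percentile 99.2.

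Chromosome 1 genes lay below WT TT2 in both G9a lines. Chromosome 1 was also below WT TT2 in the Dnmt mutants, the nearer to 0 at -0.419, which argues against loss of G9a activity as the whole cause. A trend in library composition was also argued against, since the 4 other autosomes lowest in the inhibitor control had a mean shift of -0.04 in the library labelled G9a/GLP DKO. An extra copy of chromosome 1 in cells of the WT TT2 library may be involved, as each of 3 parts of the chromosome with equal gene numbers was shifted, the nearest to 0 by -0.505. Other values go less well with it, since WT J1 lay at only -0.30 against WT TT2 and the library labelled G9a/GLP DKO and G9a CM lay at -0.23 and -0.28 against WT J1. A copy number difference of chromosome 8 in G9a CM (smallest shift of a part 0.308) stays open in the same way. These comparisons cannot tell it apart from a higher level in both WT TT2 and the library labelled G9a/GLP DKO. For chromosome 11 the smallest shift of a part between the Dnmt mutants was 0.368. Against WT TT2, however, chromosome 11 lay at 0.05 in Dnmt1/3a/3b TKO, -0.37 in Dnmt3a/3b DKO and -0.60 in WT J1, and Dnmt3a/3b DKO lay 0.20 above WT J1, so an extra copy in part of the Dnmt1/3a/3b TKO cells cannot be told apart from a lower level in the other libraries. No DNA was examined. The Y-linked genes were higher in the library labelled G9a/GLP DKO than in WT TT2 and G9a CM, and also than in the 4 inhibitor libraries of TT2 cells. Whether these lines differ in sex or in loss of the Y chromosome was not tested, and any part this plays in their other differences stays open.

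Of the 1269 genes higher in Dnmt3a/3b DKO than in WT J1, 353 were also higher than in WT TT2. Gene length bias was argued against, because with the running median over gene length removed from both comparisons 29.4% of the genes higher than in WT J1 were also higher than in WT TT2, against 27.8% without. A property of the WT J1 library, from its clone or preparation, and the strain difference between J1 and TT2 stay open. A comparison of WT TT2 with WT J1 over these genes decides neither, because genes picked for being low in the single WT J1 library tend to lie higher in any other library.

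The inhibitor control and WT TT2, both wild-type TT2 by label, differed at 3448 higher and 3009 lower genes. That WT TT2 alone stands apart was argued against, since the inhibitor control had correlations across genes of at most 0.877 with the 5 other libraries outside its set, and WT TT2 had 0.940 to 0.969 with them. A preparation or sequencing difference of the inhibitor set stays open. The lowest correlation across genes within that set, 0.981, lay above the highest between the sets, 0.883. A difference of the cells would also set the inhibitor libraries apart, so these correlations cannot tell it from a preparation difference. Gene length bias cannot be told apart from other causes, with 69.1% of genes staying past the size rule after the length trend was removed. The vehicle treatment itself is a design difference and was not tested.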
